A study of Danio rerio with 72 samples.

How the data were processed

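Expression was measured in zebrafish posterior PSM dissected from 12-somite embryos on Affymetrix zebrafish arrays, 72 arrays in 19 groups, per the labels. Embryos were raised at 24 °C. Drug treatments with RA or DAPT, and DMSO alone as their control, lasted 1.5 h or 3 h. Heat shock was at 37 °C for 30 min, with dissection 30 min or 1 h later, for dnfgfr1, DeltaTcf, dkk1, wnt8a and wild-type embryos. It lasted 1 h, with dissection 45 min or 90 min later, for gal4 and notch1a-intra embryos. RNA was extracted with Trizol, and biotin-labelled cRNA was made by in vitro transcription, per the labels' protocols. The labels call the arrays of a group biological replicates. They do not say whether a replicate number marks a shared day or clutch, and they give no scan date or batch.

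The deposited values are intensity values on a linear scale for 15617 probe sets on each array. They are MAS5 signals, per the submitters' processing notes, with the version of MAS5 not given in the sources used here. The deposited intensity values of every array had the same mean of 150 after the highest and lowest 2% were trimmed, which shows a common scaling per array. On 13 arrays, all of the DAPT experiment, the deposited values were rounded to 1 decimal. No column was left unused. Array medians on the log2 scale spanned 0.738, from 5.31 to 6.05. For arrays the number of replicates limits the precision, and no depth per array applies.

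A pseudocount of 16 was added to each value, log2 was taken, and the arrays were quantile normalized, a step set to apply where the array medians spanned more than 0.5. The pseudocount understates the changes of dim genes and puts the bottom of the scale at 4. The 115 control probe sets were left out, which left 15502. A probe set was tested where it lay above its array's median on at least 3 arrays, which held for 10126. Gene symbols came from the platform annotation and were updated through Entrez identifiers against a RefSeq gene table of assembly GRCz12tu. Of the 15502 probe sets, 10795 had 1 symbol, 135 several and 4572 none, and 10711 were matched by identifier, with 1 symbol updated. Probe sets with several symbols or none were counted but not named. Among those tested, 7568 had 1 symbol, for 6503 genes. A gene with several probe sets is represented by the brightest over all arrays. No genome build is recorded for the probe sets in the sources used here, so no coordinates are given.

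Groups were compared in limma (R 4.3.3, limma 3.58.1, statmod 1.5.0) with a model of 19 group means over all 72 arrays, empirical Bayes moderation with trend and robust settings, two-sided tests and Benjamini-Hochberg adjustment within each comparison, with a threshold of 0.05. All adjusted p for genes are from this test. The fold beside a log2 difference is 2 to that power on the pseudocount scale. There were 12 comparisons and 4 contrasts of an effect between times. Gene lists, 17 in all, were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals, with adjustment over the 204 tests. Members were counted over all probe sets tested and adjusted over the list alone. The groups, comparisons, lists, rule for named genes and the alternatives other than those named as added were fixed before the data were examined.

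The genes named for each comparison were those that the manipulation drives or targets, and the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups. To these were added up to 8 members of the pathway's own list with the smallest p and up to 4 members of another list where it is described. Genes with only a placeholder name were counted but not named, and 1 gene that the rule selects is not reported here. Chance alone separates the arrays of 2 groups in 2.86% of cases for 4 against 4, 5.71% for 4 against 3 and 13.3% for 2 against 4.

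The test was checked on simulated data with known changes. For RA at 1.5 h it recovered 37.3%, 77.6% and 98.5% of probe sets changed by 1.5-fold, 2-fold and 4-fold, and 1.32% of its calls were false. For DAPT at 3 h, with the fewest arrays, it recovered 19.4%, 62.7% and 95.5%, and 4.72% of its calls were false. Among the comparisons simulated, the lowest share of false calls was 0.676%, for dnfgfr1 at 30 min. Shares above the threshold of 0.05 were 7.24% for notch1a-intra at 90 min and 6.17% at 45 min. So were 6.83% for dkk1 and 5.62% each for wnt8a and for wild type at 1 h against 30 min. These shares describe the simulated data alone.

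Alternatives were the deposited scaling without quantile normalization, median centring of each array, pseudocounts of 1 and 64, no filter and a stricter filter, a fit of the compared groups alone, the replicate number as a block in that fit, array quality weights, moderation without trend and robust settings, and each array left out in turn. Added after the data were seen were the comparisons among the Wnt groups, wild type at 30 min as their control, the notch1a-intra comparison without the 2 libraries of low notch1a, and the averaging of close replicate pairs, the last also for the list tests of the Notch comparisons. Whether replicate numbers pair the samples was checked from the correlation of same-numbered arrays after removal of group means. For notch1a-intra and gal4 at 45 min all 4 pairs had r of 0.21 to 0.312, and 3 of them had their highest r with the same number. Pairing is thus possible there but not settled. The blocked values are given beside that comparison, with its list tests adjusted over the 17 lists and not over the 204 tests. In no other comparison with at least 3 pairs did every pair exceed 0.1. Overlaps of calls were set against independent lists, against 100 draws of unchanged groups with the same controls, and against the 6 ways of splitting 4 controls into pairs. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.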

Results

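Gene expression was measured in 72 arrays of zebrafish tissue, each hybridised with amplified RNA from the posterior presomitic mesoderm (PSM), the unsegmented tail-bud tissue that gives rise to somites. The tissue came from embryos at the 12-somite stage and fell into 19 groups. Wild-type embryos were exposed to retinoic acid (RA), to DAPT, an inhibitor of the gamma-secretase that releases active Notch, or to the solvent DMSO alone, for 1.5 h or 3 h. Embryos carrying heat-inducible transgenes were shocked and dissected later. The transgenes encoded a dominant-negative Fgf receptor (dnfgfr1), DeltaTcf, the secreted Wnt inhibitor dkk1 or the ligand wnt8a. In a further pair of groups gal4 drove the intracellular domain of Notch (notch1a-intra). Wild-type and gal4 embryos treated with the same heat shock were the controls. Each group held 4 arrays, except RA at 3 h and DAPT at 1.5 h with 3 each and DAPT at 3 h with 2. Levels are given as log2 signal, on which the bottom of the scale is 4, and errors beside log2 differences are standard errors from the fit. The number of arrays per group limits the precision of every value.

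The genes that the manipulations drive or target were examined in every group first. The stress gene hsp70.3 had group means of 8.98 to 12.63 in the heat-shocked groups and 4.64 to 5.77 in the groups treated with drug or DMSO. The signal of dkk1b, whose coding sequence the dkk1 transgene carries, was 13.05 ± 0.08 (SD, n = 4) in the libraries labelled dkk1 and 5.44 ± 0.51 (SD, n = 4) in the heat-shocked wild type. It was also 12.81 ± 0.09 (SD, n = 4) in the libraries labelled DeltaTcf, against 5.53 ± 0.22 (SD, n = 4) in the libraries labelled wnt8a, so directions drawn from the libraries labelled DeltaTcf rest on a label that this gene puts in doubt. The libraries labelled notch1a-intra had notch1a at 11.85 ± 0.06 (SD, n = 4) at 90 min, but at 45 min replicates 1 and 3 lay at 11.64 and 11.83 and replicates 2 and 4 no higher than 8.29, near the gal4 mean of 7.67 ± 0.55 (SD, n = 4). Neither fgfr1a nor tcf7l1a differed from wild type in the dnfgfr1 and DeltaTcf libraries, but their probe sets may lie outside the transgenes and so check nothing. No probe set analysed here was named wnt8a, and that label could not be checked.

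**Figure D1:**
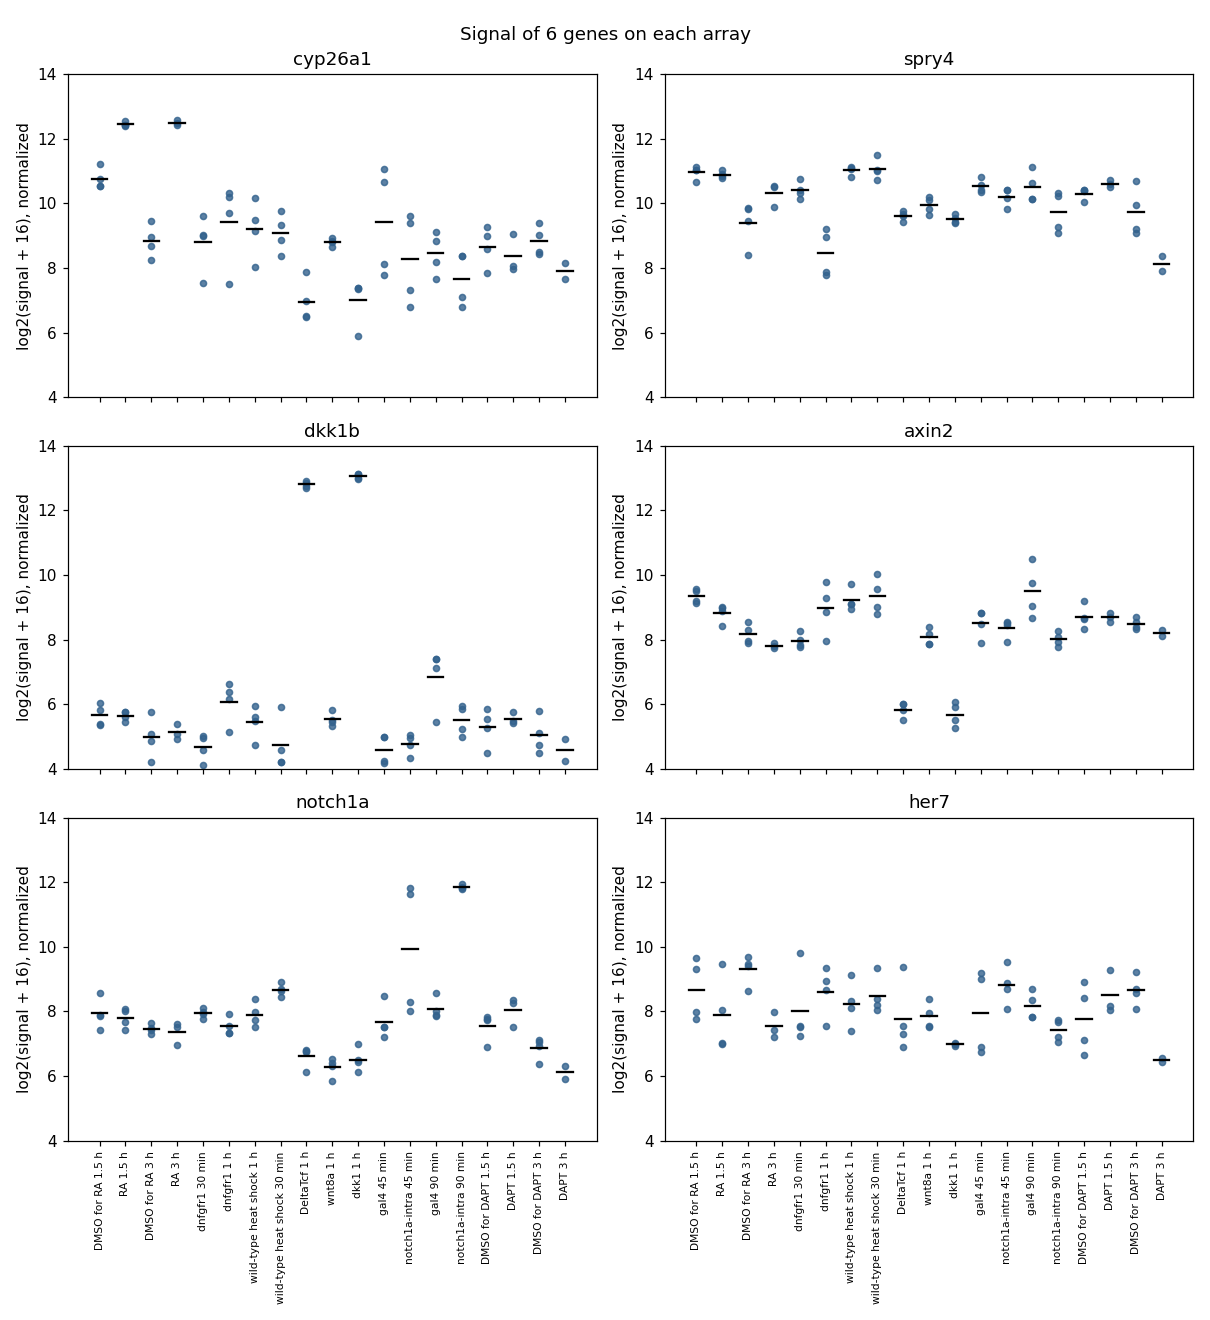
Normalized log2 signal of cyp26a1, spry4, dkk1b, axin2, notch1a and her7 on each of the 72 arrays, with the 19 groups along the horizontal axis, a point per array and a bar at each group mean. dkk1b lies at 13.05 in the dkk1 and 12.81 in the DeltaTcf group, and notch1a splits into 2 high and 2 low arrays at 45 min.

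The first comparison asked which PSM genes respond to 1.5 h of RA (4 arrays against 4). The retinaldehyde reductase gene dhrs3a rose 23.9-fold (log2 4.58 ± 0.24, adjusted p = 2.9e-23). The nuclear receptor genes nr2f1a and nr2f5 rose 5.7-fold (2.51 ± 0.20, adjusted p = 8.07e-15) and 5.23-fold (2.39 ± 0.33, adjusted p = 2.05e-07), and the anterior Hox gene hoxa3a rose 5.48-fold (2.46 ± 0.21, adjusted p = 8.92e-14). The segmentation gene mespaa fell 6.88-fold (-2.78 ± 0.29, adjusted p = 8e-11). The RA-degrading enzyme gene cyp26a1 had the higher level in all 4 RA arrays, at 12.46 ± 0.07 against 10.77 ± 0.32 (SD), but missed the threshold in the pooled fit (1.69 ± 0.58, adjusted p = 0.0856). It passed in a fit of the 2 groups alone (adjusted p = 0.000193, and from 0.000193 to 0.22 over its alternatives).

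Of 30 RA pathway genes tested at 1.5 h, 10 rose and 2 fell (16 and 3 adjusted over the list alone). The list as a whole was shifted up (adjusted p = 3.84e-18, and adjusted p = 0.000145 with an estimated correlation). Among them hoxb1a, meis2b and meis3 rose by 1.71 ± 0.16, 2.58 ± 0.28 and 2.14 ± 0.24, while hoxc6a fell by 1.12 ± 0.17. Of 28 genes of paraxial mesoderm and somites, 10 fell and 0 rose (11 fell and 1 rose adjusted over the list alone), with adjusted p = 1.2e-11 for the list and adjusted p = 0.00816 with an estimated correlation. These included the transcription factor genes snai1a (-1.99 ± 0.22) and foxc1b (-1.44 ± 0.21) and the ephrin gene efnb2b (-1.36 ± 0.19). Of 20 posterior Hox genes 6 fell and 0 rose (10 and 0 adjusted over the list alone), among them hoxc11a (-1.97 ± 0.26), hoxa10b (-1.24 ± 0.13) and hoxc9a (-0.87 ± 0.16). That list had adjusted p = 3.35e-07, but adjusted p = 0.261 with an estimated correlation.

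Markers of other tissues moved in the same arrays. Of 22 muscle genes 7 fell and 0 rose (16 and 0 adjusted over the list alone), among them the muscle determination gene myf5 (-1.25 ± 0.22) and the myosin chaperone gene unc45b (-0.80 ± 0.15), with adjusted p = 5.99e-09 for the list and adjusted p = 0.31 with an estimated correlation. Of 7 pronephros genes 2 rose (2 adjusted over the list alone), of which gata3 rose by 1.39 ± 0.27, with adjusted p = 0.000958 and adjusted p = 0.488 with an estimated correlation. Of 18 epidermis genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.00849 and adjusted p = 0.695 with an estimated correlation. None of 18 blood and endothelium genes was called, with adjusted p = 0.0138 for the list and adjusted p = 0.748 with an estimated correlation.

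Over all 10126 probe sets tested, 240 were higher and 199 lower after 1.5 h of RA (439 in all, adjusted p under 0.05). The total was 246 without replicate 3 of the DMSO group and 291 without its replicate 4, and 1068 with array quality weights. Of the 33 named genes that were called, 25 kept the call in every alternative run for them. The stricter filter removed 10 of the 33, of which 9 are among the 25, and such tallies below leave that alternative out for the genes it removed.

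At 3 h (3 arrays against 4) dhrs3a rose 75.6-fold (6.24 ± 0.26, adjusted p = 1.9e-28), meis2b 26.1-fold (4.71 ± 0.30, adjusted p = 9.34e-20) and rx3, a homeobox gene of the eye field, 19.4-fold (4.28 ± 0.25, adjusted p = 1.23e-21). cyp26a1 rose 12.7-fold (3.66 ± 0.62, adjusted p = 2.36e-05), at 12.49 ± 0.07 against 8.83 ± 0.50 in DMSO (SD), so that its RA level was near that at 1.5 h (12.46) and its DMSO level below that at 1.5 h (10.77). mespaa fell 11.4-fold (-3.51 ± 0.32, adjusted p = 1.85e-13) and hoxc11a 13.2-fold (-3.72 ± 0.28, adjusted p = 1.97e-16), with smaller falls of -0.76 and -2.25 at its other probe sets. The polycomb gene phc2a fell 6.26-fold (-2.64 ± 0.12, adjusted p = 3.71e-26).

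Of the 30 RA pathway genes 14 rose and 3 fell at 3 h (15 and 4 adjusted over the list alone), with adjusted p = 2.34e-29 and adjusted p = 4.14e-06 with an estimated correlation. cyp26b1, another RA-degrading enzyme gene, rose by 2.28 ± 0.24 at its brightest probe set and by 5.32 and 5.26 at the others. Of 20 posterior Hox genes 10 fell and 0 rose (13 and 2 adjusted over the list alone), including hoxd11a (-2.44 ± 0.25), hoxa10b (-1.84 ± 0.14) and hoxa9b (-1.26 ± 0.16), with adjusted p = 9.04e-22 and adjusted p = 0.0028 with an estimated correlation. Of 28 paraxial mesoderm and somite genes 8 fell and 1 rose (10 and 2 adjusted over the list alone), including foxc1b (-1.76 ± 0.22), the T-box gene tbx16l (-1.23 ± 0.14) and msgn1 (-0.68 ± 0.09), with adjusted p = 4.37e-08 and adjusted p = 0.0374 with an estimated correlation. Of 25 FGF pathway genes 6 rose and 0 fell (8 and 2 adjusted over the list alone), among them the ligand genes fgf8a (3.27 ± 0.59) and fgf10a (1.92 ± 0.40) and the phosphatase gene dusp1 (1.66 ± 0.16). The FGF list had adjusted p = 0.0189, and adjusted p = 0.261 with an estimated correlation.

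Of 22 muscle genes 2 fell (4 fell and 1 rose adjusted over the list alone), with adjusted p = 0.00272 and adjusted p = 0.633 with an estimated correlation. Of 7 pronephros genes 3 rose (3 adjusted over the list alone), with adjusted p = 0.0301 and adjusted p = 0.597 with an estimated correlation. Of 9 yolk, liver and hatching gland genes 1 fell (3 adjusted over the list alone), with adjusted p = 0.0295 and adjusted p = 0.488 with an estimated correlation. Each of the genes called in these lists lost its call in at least 1 alternative. In all, 226 probe sets were higher and 147 lower (373), and the total was 725 with array quality weights. Of the 36 named genes called, 26 kept the call in every alternative run for them (8 of these without the stricter filter).

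**Figure D2:**
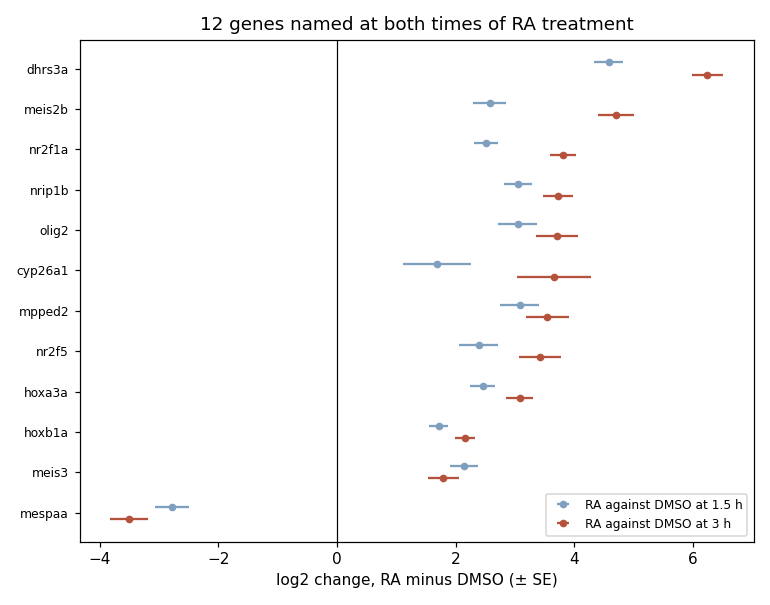
Log2 difference between RA and DMSO at 1.5 h and at 3 h, with standard errors from the fit, for the 12 genes named at both times. dhrs3a has the largest rise at both times, 4.58 and 6.24, and mespaa falls by 2.78 and by 3.51.

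The difference between the RA effects was tested directly, as the effect at 3 h minus that at 1.5 h. The effect was larger at 3 h for dhrs3a (by 1.66 ± 0.36), meis2b (2.13 ± 0.41) and rx3 (2.78 ± 0.34), and more negative for hoxc11a (-1.75 ± 0.38), hoxd11a (-1.78 ± 0.34) and phc2a (-1.26 ± 0.17). The difference between times did not pass for cyp26a1 (1.975, adjusted p = 0.392) or mespaa (-0.72 ± 0.43, adjusted p = 0.615). In all, 37 probe sets had a higher and 36 a lower effect at 3 h (50.7% higher). The share was 38.5% with the deposited scaling and 64.1% with median centring. The total of 73 was 48 without replicate 1 of the 3 h DMSO group and 43 and 46 without replicates 1 and 2 of RA at 3 h, and 362 with array quality weights.

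The dnfgfr1 comparison asked which genes depend on Fgf receptor signalling shortly after the receptor is blocked. At 30 min after heat shock (4 arrays against 4), spry4, a feedback inhibitor of Fgf signalling, was at 10.41 ± 0.25 against 11.07 ± 0.33 in wild type (SD), a difference that did not pass (-0.66 ± 0.28, adjusted p = 0.22). None of 25 FGF pathway genes was called (0 rises and 0 falls), and the list as a whole had adjusted p = 0.447. The Wnt feedback gene axin2 fell 2.6-fold (-1.38 ± 0.27, adjusted p = 0.000723). The heat shock regulator gene hsf1 rose 4.17-fold (2.06 ± 0.22, adjusted p = 2.76e-10). The epidermis list, with 1 of 18 genes called, a rise of lgals3b (2.59 ± 0.48), had adjusted p = 0.00732 and adjusted p = 0.704 with an estimated correlation. In wild type itself lgals3b was lower at 30 min than at 1 h, as given below. In all 167 probe sets were higher and 137 lower (304). The total was 201 without replicate 4 of the dnfgfr1 group and 861 with array quality weights.

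At 1 h (4 arrays against 4) spry4 fell 5.94-fold (-2.57 ± 0.28, adjusted p = 8.34e-10) and mespaa 6.16-fold (-2.62 ± 0.29, adjusted p = 1.59e-09). The cytokine signalling inhibitor gene socs3b fell 3.13-fold (-1.65 ± 0.27, adjusted p = 3.9e-05). Of 25 FGF pathway genes 3 fell and 0 rose (3 fell and 1 rose adjusted over the list alone), namely spry4, the immediate early gene ier2a (-2.83 ± 0.29) and the ERK phosphatase gene dusp6 (-1.49 ± 0.19, and -0.61 at its other probe set). The calls of ier2a and dusp6 were lost in a fit of the 2 groups alone (adjusted p = 0.0902 and 0.115, over ranges of 1.29e-15 to 0.132 and 2.71e-11 to 0.18 for their alternatives). The list had adjusted p = 0.0295, but adjusted p = 0.488 with an estimated correlation. hsf1 rose 4.13-fold (2.05 ± 0.22, adjusted p = 3.37e-10). Of 28 paraxial mesoderm and somite genes 2 fell (3 adjusted over the list alone), with adjusted p = 0.0138 and adjusted p = 0.568 with an estimated correlation. None of 31 neural genes was called, with adjusted p = 0.00645 for the list and adjusted p = 0.633 with an estimated correlation.

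In all, 184 probe sets were higher and 162 lower in dnfgfr1 at 1 h (346). The total was 595 with array quality weights and 229 in a fit of the 2 groups alone. The effect on spry4 was more negative at 1 h than at 30 min (by -1.91 ± 0.39, adjusted p = 0.00594), as was that on mespaa (-2.14 ± 0.41, adjusted p = 0.00283). A total of 19 probe sets had a higher and 19 a lower effect at 1 h (38 in all, and 141 with array quality weights). axin2, which fell at 30 min, was not called at 1 h (-0.25, adjusted p = 0.764), and its difference between times did not pass (1.13 ± 0.38, adjusted p = 0.257). The calls at 30 min and 1 h shared 94 probe sets in the same direction, against 5.23 from independent lists, and 3 in opposite directions, against 5.16. That pair of comparisons was chosen after the data were seen. Each sets the dnfgfr1 line against wild type, so the overlap cannot part an effect of the transgene from a fixed difference between the lines.

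The Wnt comparisons asked how blocking or raising Wnt signalling changes the PSM 1 h after heat shock, each with 4 arrays against the same 4 wild-type arrays. In the libraries labelled dkk1, the Wnt feedback gene axin2 fell 11.6-fold (-3.54 ± 0.27, adjusted p = 8.46e-16), and sp5a, a transcription factor gene driven by Wnt, fell 7.52-fold (-2.91 ± 0.36, adjusted p = 1.23e-08). The RA-degrading enzyme gene cyp26a1 fell 4.6-fold (-2.20 ± 0.58, adjusted p = 0.00316) and notch3 fell 4.99-fold (-2.32 ± 0.33, adjusted p = 1.94e-07), a gene that was lower in the DeltaTcf and wnt8a libraries too (-1.986 and -1.583). dkk1b rose 196-fold (7.62 ± 0.34, adjusted p = 1.32e-26). Of 27 Wnt pathway genes 2 rose and 7 fell (2 and 9 adjusted over the list alone), the falls including axin1 (-1.25 ± 0.19), the receptor gene fzd10 (-0.61 ± 0.12) and the ligand gene wnt5b (-1.08 ± 0.22), and the list as a whole had adjusted p = 0.289. Over all probe sets 1269 were higher and 1225 lower (2494), the largest total among the 12 comparisons. Of these, 915 were called in the same direction in the DeltaTcf and wnt8a libraries too. The labels give no batch, so differences of these Wnt groups from wild type cannot be parted from one between library batches.

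In the libraries labelled DeltaTcf, axin2 fell 10.4-fold (-3.38 ± 0.27, adjusted p = 8.6e-15), sp5a 6.61-fold (-2.72 ± 0.36, adjusted p = 1.16e-07) and fgf8a 5.81-fold (-2.54 ± 0.54, adjusted p = 0.000443). cyp26a1 fell 4.73-fold (-2.24 ± 0.58, adjusted p = 0.0034). dkk1b rose 165-fold in these libraries (7.37 ± 0.34, adjusted p = 7.53e-26). Of the 27 Wnt pathway genes 2 rose and 6 fell (2 and 8 adjusted over the list alone), the falls including axin1 (-0.91 ± 0.19) and fzd10 (-0.65 ± 0.12), and the list had adjusted p = 0.241. A total of 1005 probe sets were higher and 1077 lower (2082).

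In the libraries labelled wnt8a, axin2 also fell against wild type, 2.2-fold (-1.14 ± 0.27, adjusted p = 0.0015), as did axin1 (-0.86 ± 0.19) and wnt5b (-0.78 ± 0.22). The cofactor gene hcfc1b fell 7.29-fold (-2.87 ± 0.31, adjusted p = 8.58e-10), with -1.80 and -0.10 at its other probe sets. Of the 27 Wnt pathway genes 1 rose and 4 fell (1 and 4 adjusted over the list alone), with adjusted p = 0.378 for the list. None of the 17 lists was shifted as a whole in any of these 3 groups. A total of 794 probe sets were higher and 850 lower (1644), and the total was 2539 with array quality weights and 2643 against the wild-type arrays taken 30 min after heat shock, a control chosen after the data were seen.

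The 3 Wnt groups moved together against their shared controls. DeltaTcf and dkk1 shared 1381 calls in the same direction, against 256 from independent lists, and 4 in opposite directions, against 257. The log2 differences correlated across probe sets, which are not independent replicates, at r = 0.768, with a covariance of 0.191. Unchanged groups simulated against the same controls gave r = 0.467, a covariance of 0.0242 and 0 shared calls in 100 draws. They carry no differences of their own, so their r and their count cannot be compared with these. With the controls split into separate pairs, the mean over the 6 splits was 674.5 shared calls and a covariance of 0.167. The wnt8a and dkk1 libraries shared 1175 calls in the same direction, against 202, and 2 in opposite directions, against 203 (r = 0.701, covariance 0.161, and 548 calls with covariance 0.137 with split controls). The wnt8a and DeltaTcf libraries shared 1082, against 169, and 1 in opposite directions, against 169 (r = 0.676, covariance 0.145, and 466.2 calls with covariance 0.121 with split controls). A set of 915 probe sets was called in the same direction in all 3 groups, 411 higher and 504 lower, where independent lists would share 9.88 and 10.9.

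The dnfgfr1 libraries at 1 h, with 346 calls in all, were set beside dkk1 and DeltaTcf. They shared 115 calls with dkk1 in the same direction, against 42.7 from independent lists, and 23 in opposite directions, against 42.6 (r = 0.219, covariance 0.0411, and 28.5 calls with covariance 0.017 with split controls). With DeltaTcf they shared 99, against 35.5, and 20 in opposite directions, against 35.6 (r = 0.191, covariance 0.0335, and 23 calls with covariance 0.00935 with split controls). Unchanged groups simulated against the same controls gave r = 0.467, above both correlations, a covariance of 0.0242 and 0 shared calls. Such groups carry no differences of their own, so their r cannot be compared with these, and r does not tell whether an effect was shared. Both covariances lay above the simulated value. The counts of shared calls did too, but groups without differences yield hardly any calls, so that comparison decides nothing. With split controls 8.83 calls went opposite ways with dkk1 and 8.33 with DeltaTcf, against the 28.5 and 23 in the same direction.

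Because all 3 groups differed from wild type in common, they were also compared with each other, a choice made after the data were seen (4 arrays against 4 each). Against the wnt8a libraries, those labelled dkk1 had lower axin2 (5.27-fold, -2.40 ± 0.27, adjusted p = 6.15e-09), sp5a (6.13-fold, -2.62 ± 0.36, adjusted p = 1.56e-06), sp5l (-1.10 ± 0.26) and six4a (-2.02 ± 0.34), and higher dkk1b (184-fold). Those labelled DeltaTcf likewise had lower axin2 (4.74-fold, -2.25 ± 0.27, adjusted p = 3.63e-08), sp5a (5.39-fold, -2.43 ± 0.36), sp5l (-1.52 ± 0.26) and fgf8a (-2.72 ± 0.54). Against wnt8a, cyp26a1 was called neither in dkk1 nor in DeltaTcf (-1.80 and -1.84, adjusted p = 0.069 and 0.072), and notch3 and axin1 were not called in dkk1 (-0.74 and -0.39, adjusted p = 0.238 and 0.286). Of the 27 Wnt pathway genes 1 rose and 4 fell in each of these comparisons (1 and 5 adjusted over the list alone for dkk1, 2 and 5 for DeltaTcf). Between DeltaTcf and dkk1 no Wnt pathway gene was called (0 rises and 0 falls), while the neurotrophin receptor homologue gene nradd was 16.3-fold higher (4.03 ± 0.92) in the libraries labelled DeltaTcf.

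The dkk1 libraries differed from wnt8a at 156 higher and 176 lower probe sets (332), DeltaTcf from wnt8a at 124 and 132 (256), and DeltaTcf from dkk1 at 179 and 173 (352). Median centring moved the share of higher calls from 48.4% to 36.8% for DeltaTcf against wnt8a and from 50.9% to 38.7% for DeltaTcf against dkk1. The dkk1 against wnt8a total was 206, 199 and 211 without wnt8a replicates 1, 2 and 3. For DeltaTcf against wnt8a it was 161 without DeltaTcf replicate 3 and 167 without wnt8a replicate 2. For DeltaTcf against dkk1 it was 227 and 191 without DeltaTcf replicates 1 and 3, and 221 without dkk1 replicate 4. Only 1 neural gene of 31 fell in dkk1 and in DeltaTcf against wnt8a (2 and 3 adjusted over the list alone), and the list had adjusted p = 0.0393 and 0.00936 but adjusted p = 0.966 with an estimated correlation in both.

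**Figure D3:**
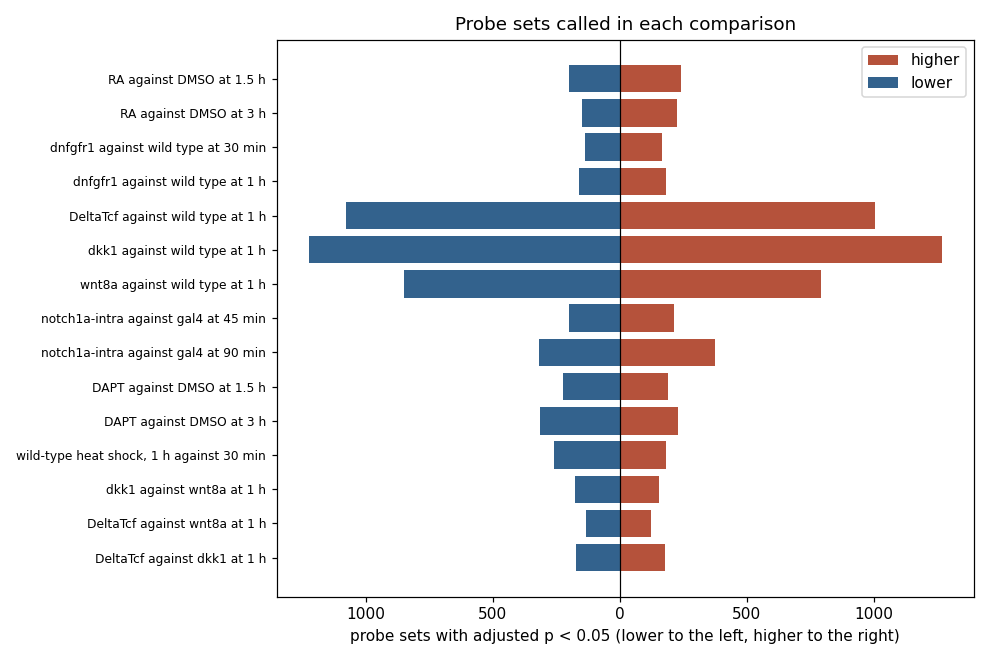
Number of probe sets called higher (up) and lower (down) at an adjusted p under 0.05 in each of the 12 comparisons and in the 3 comparisons within the Wnt groups that were added later. The dkk1 comparison against wild type has the most calls, 1269 up and 1225 down.

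The notch1a-intra comparison asked what active Notch changes in the PSM. At 90 min (4 arrays against 4) notch1a rose 13.6-fold (3.76 ± 0.41, adjusted p = 1.62e-09, and 5.41 at its other probe set). Hairy-related transcription factor genes that Notch activates rose with it, her4.5 by 7.04-fold (2.82 ± 0.37, adjusted p = 1.4e-07), hey1 by 5.62-fold (2.49 ± 0.45, adjusted p = 0.000103) and her15.2 by 4.35-fold (2.12 ± 0.32, adjusted p = 4.94e-06). The intermediate filament gene inaa rose 30.4-fold (4.92 ± 0.50, adjusted p = 2.31e-10). The lysosomal protein gene psap fell 4.21-fold (-2.08 ± 0.15, adjusted p = 1.04e-16). Of 30 genes of Notch signalling and the segmentation clock 6 rose and 1 fell (9 and 4 adjusted over the list alone), with adjusted p = 0.00645 and adjusted p = 0.568 with an estimated correlation. In all 377 probe sets were higher and 319 lower (696). The total was 435 without gal4 replicate 3, 434 and 459 without notch1a-intra replicates 1 and 3, 329 in a fit of the 2 groups alone and 218 with close replicate pairs averaged. Of the 21 named genes called, 11 kept the call in every alternative run for them (4 without the stricter filter).

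Pairs of replicates lay close together in 3 of the 4 groups of this experiment, and the labels do not say whether they share embryos or RNA. If they do, those groups hold 2 or 3 separate samples and not 4, and the p values of this section that count 4 arrays are too small. With close pairs averaged, a choice made after the data were seen, and adjustment over the 17 lists of the comparison alone, the Notch and segmentation clock list had adjusted p = 0.00269 at 90 min. At 45 min the values were 0.00433 for that list, 0.000242 for muscle, 1.93e-06 for blood and endothelium, 0.00433 for p53 and apoptosis, 0.0324 for epidermis and 0.00433 for cell cycle, a list that did not pass in the main test (adjusted p = 0.0911).

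At 45 min (4 arrays against 4) notch1a rose 4.82-fold on average (2.27 ± 0.41, adjusted p = 0.00029) over the 2 high and 2 low libraries. The call was lost in a fit of the 2 groups alone (adjusted p = 0.299) and with the replicate block (adjusted p = 0.25). her4.5, given here because it rose at 90 min, a choice made after its values were seen, rose at 45 min too (1.43, adjusted p = 0.014, over a range of 1.3e-07 to 0.345 for its alternatives). Its call was lost without notch1a-intra replicate 1 or 3 (adjusted p = 0.143 and 0.133), in a fit of the 2 groups alone (0.345), with the block (0.275), with close pairs averaged (0.122), with array weights (0.243) and with a pseudocount of 1 (0.0813). hey1 and her15.2 were not called (1.15 ± 0.45 and 0.99 ± 0.32, adjusted p = 0.125 and 0.0655). The growth factor binding protein gene igfbp1a fell 4.08-fold (-2.03 ± 0.30, adjusted p = 6.05e-06) and the transcription factor gene cebpb fell 3.76-fold (-1.91 ± 0.32, adjusted p = 6.75e-05). Of the 26 named genes called at 45 min, 4 kept the call in every alternative run for them, igfbp1a, cebpb, jam2a and krt94, the last without the stricter filter. Of 30 Notch and segmentation clock genes 1 rose (1 adjusted over the list alone), which was notch1a itself, with adjusted p = 0.0101 and adjusted p = 0.568 with an estimated correlation (adjusted p = 0.0175 with the block, where all list values are adjusted over the 17 lists of this comparison alone).

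Markers of other tissues moved at 45 min too, and the values with the block are again adjusted over the 17 lists alone. Of 22 muscle genes 7 rose and 1 fell (10 and 1 adjusted over the list alone). The rises included the muscle structural genes myl10 (2.70 ± 0.66) and tpma (1.89 ± 0.47), whose calls were lost in 2 and 1 of 20 alternatives, and myod1, acta1a, ttn.2 and tnnc2.2, whose calls were lost in 6, 8, 6 and 8, while the remaining rise was not run through them. The fall was of jam2a, a cell adhesion gene of muscle precursors (-1.61 ± 0.30), and the list had adjusted p = 6.05e-05, adjusted p = 0.568 with an estimated correlation and adjusted p = 1.6e-14 with the block. Of 18 blood and endothelium genes 1 fell (8 adjusted over the list alone), cahz, whose call was lost in 4 of 19 alternatives, with adjusted p = 5.84e-06, adjusted p = 0.488 with an estimated correlation and adjusted p = 3.55e-11 with the block. Of 20 p53 and apoptosis genes 4 fell (5 adjusted over the list alone), gadd45ga, mdm4, cdkn1bb and pmaip1, each losing its call in at least 4 alternatives, with adjusted p = 0.00849, adjusted p = 0.488 with an estimated correlation and adjusted p = 0.000626 with the block. Of 18 epidermis genes 1 fell (1 adjusted over the list alone), the keratin gene krt94 (-1.53 ± 0.21), with adjusted p = 0.0499, adjusted p = 0.773 with an estimated correlation and adjusted p = 0.00124 with the block.

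In all, 216 probe sets were higher and 198 lower at 45 min (414, of which 52.2% higher, or 62.6% with median centring). With the replicate number as a block, which may pair these samples, the total was 158. It was 244 without notch1a-intra replicate 3, 61 in a fit of the 2 groups alone, 64 with close replicate pairs averaged, 2651 with array quality weights and 1187 without the low-notch1a replicates 2 and 4. That last run left only notch1a-intra replicates 1 and 3, themselves a close pair, so its p values may be too small as well. Its total cannot be parted from the difference of replicates 1 and 3 from replicates 2 and 4, given below. The effect at 90 min exceeded that at 45 min for inaa (3.51) and gcdhb (2.37) and was more negative for psap (-2.48). These differences mix time with the presence of 2 libraries at 45 min whose notch1a lay near the gal4 level, and for which it is not settled that they carry the transgenes. Without those libraries the difference was 1.84 for inaa, no longer called (adjusted p = 0.138), 2.595 for gcdhb and -2.62 for psap, and with close pairs averaged inaa and gcdhb were not called (adjusted p = 0.052 and 0.0866); both settings were chosen after the data were seen. In all 31 probe sets had a higher and 39 a lower effect at 90 min (70). That total was 125 without the low-notch1a libraries, 14 with close pairs averaged, 21 in a fit of the compared groups alone and 1341 with array quality weights. It was 34 and 129 without gal4 45 min replicates 2 and 4, 108 without notch1a-intra 45 min replicate 1, 108 and 31 without gal4 90 min replicates 2 and 3, and 45 and 39 without notch1a-intra 90 min replicates 2 and 4.

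The DAPT comparison asked what the loss of Notch cleavage changes. At 1.5 h (3 arrays against 4) the Notch feedback gene nrarpa fell 1.75-fold (-0.80 ± 0.15, adjusted p = 0.000895), with -0.34 and -0.85 at its other probe sets, and her7, an oscillating gene of the segmentation clock, was at 8.50 ± 0.67 against 7.77 ± 1.07 (SD) and was not called (adjusted p = 0.57). The nrarpa call was lost in a fit of the 2 groups alone (adjusted p = 0.0769, over a range of 0.000187 to 0.185 for its alternatives). Of 30 Notch and segmentation clock genes 1 fell (1 adjusted over the list alone), and the list had adjusted p = 0.128. Of 20 posterior Hox genes 4 rose (8 adjusted over the list alone), hoxd9a, hoxa10b, hoxa9b and hoxc11b, by 0.48 to 1.08, each losing its call in at least 7 alternatives, with adjusted p = 0.000336 for the list and adjusted p = 0.488 with an estimated correlation. In all 189 probe sets were higher and 225 lower (414, of which 45.7% higher, or 22% with median centring). The total was 262 without DMSO replicate 3, 225 without DAPT replicate 1, 196 with array quality weights and 7 in a fit of the 2 groups alone, and none of the 18 named genes called kept the call in every alternative run for them.

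At 3 h (2 arrays against 4) genes of the paraxial mesoderm fell. The T-box genes tbx16 and tbx16l fell 2.23-fold (-1.16 ± 0.19, adjusted p = 4.37e-05) and 2.05-fold (-1.04 ± 0.16, adjusted p = 2.3e-05), and epha4a, which encodes an ephrin receptor of somite boundaries, fell 3.77-fold (-1.92 ± 0.31, adjusted p = 5.24e-05), though its other probe set was at 0.13. her7 fell 4.46-fold (-2.16 ± 0.67, adjusted p = 0.0435). Its call was lost without DMSO replicates 2, 3 and 4 (adjusted p = 0.0611, 0.103 and 0.062), without DAPT replicates 1 and 2 (0.191 and 0.136), and with the deposited scaling, median centring, a pseudocount of 64 and array weights (0.0669, 0.0594, 0.0661 and 0.49). The cathepsin gene ctss2.1 rose 5.8-fold (2.54 ± 0.32, adjusted p = 4.29e-07).

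Of 28 paraxial mesoderm and somite genes 9 fell and 0 rose at 3 h of DAPT (10 and 0 adjusted over the list alone), with adjusted p = 2.19e-09 and adjusted p = 0.0216 with an estimated correlation. Of 27 Wnt pathway genes 4 fell (8 adjusted over the list alone), with adjusted p = 0.000396 and adjusted p = 0.005 with an estimated correlation. They were fzd7b (-1.06 ± 0.19), fzd10 (-0.63 ± 0.15), notum1b (-1.56 ± 0.40) and wnt5b (-0.97 ± 0.28), of which fzd7b lost its call only without DAPT replicate 1 (adjusted p = 0.0852, the highest over its alternatives) and the others in at least 4 alternatives each. Of 30 Notch and segmentation clock genes 1 fell (0 adjusted over the list alone), with adjusted p = 0.273. The gene her4.5, outside that list and looked at here after its values were seen, was lower in DAPT. It was at 4.53 ± 0.03 (SD, n = 2) against 5.89 ± 0.215 (SD, n = 4) in DMSO. The DAPT level lay near the bottom of the scale. hey1 and nrarpa differed by -0.09 and -0.06 and were not called (adjusted p = 0.954 and 0.889).

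Markers of other tissues were higher in the same 2 arrays. It was not settled whether these dissections held the same mix of tissue as the controls. The falls above thus cannot be assigned to the loss of Notch cleavage alone. Of 18 blood and endothelium genes 4 rose (4 adjusted over the list alone), cahz (1.71 ± 0.36), tfa, epb41b and the globin gene hbbe3, whose calls were lost in 4, 7, 7 and 8 of 15 alternatives, with adjusted p = 5.84e-06 and adjusted p = 0.493 with an estimated correlation. Of 9 yolk, liver and hatching gland genes 3 rose (5 adjusted over the list alone), with adjusted p = 0.000752 and adjusted p = 0.261 with an estimated correlation. They were the fatty acid binding protein gene fabp1b.1 (1.71 ± 0.29), which among the 15 alternatives run for it lost its call in a fit of the 2 groups alone (adjusted p = 0.0671, the highest over its alternatives), apoa1a, which lost it in 4 alternatives, and tfa again. Of 7 pronephros genes 2 rose (4 adjusted over the list alone), with adjusted p = 0.00142 and adjusted p = 0.488 with an estimated correlation. These were ret and hnf1bb, whose differences turned to -0.13 and -0.20 without DAPT replicate 1.

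In all 230 probe sets were higher and 312 lower at 3 h of DAPT (542). The total was 170 without DAPT replicate 1, 315 with median centring, 78 in a fit of the 2 groups alone and 35 with array quality weights, and 7 of the 29 named genes called kept the call in every alternative run for them (2 without the stricter filter). The DAPT effect differed between 3 h and 1.5 h at 180 higher and 221 lower probe sets (401). That total was 218 without DAPT 3 h replicate 1, 221 with median centring, 42 with array quality weights and 11 in a fit of the compared groups alone. The effect at 3 h was more negative for epha4a (by -1.64) and higher for ctss2.1 (2.61).

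Gain and loss of Notch were set side by side through notch1a-intra at 90 min and DAPT at 3 h, which have separate controls. They shared 11 calls in the same direction, against 18.4 from independent lists, and 21 in opposite directions, against 18.9, and their log2 differences had r = -0.0316 across probe sets. RA at 3 h and dnfgfr1 at 1 h shared 12 calls in the same direction, against 6.46, and 11 in opposite directions, against 6.29 (r = -0.015).

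The wild-type heat-shock groups were compared at 1 h against 30 min (4 arrays against 4) to give the background of recovery from heat. The gene sde2 rose 9.39-fold (3.23 ± 0.41, adjusted p = 3.71e-07, but -0.59 at its other probe set), and the lectin gene lgals3b rose 5.81-fold (2.54 ± 0.48, adjusted p = 0.000537). The amino acid transporter gene slc38a2 fell 3.33-fold (-1.74 ± 0.33, adjusted p = 0.000498). Of 30 heat shock and stress genes 2 fell (3 adjusted over the list alone), and the list had adjusted p = 0.359. The epidermis list, of whose 18 genes lgals3b alone was called (1 rise, and 1 adjusted over the list alone), had adjusted p = 0.000336 and adjusted p = 0.568 with an estimated correlation. In all 183 probe sets were higher and 259 lower (442, of which 41.4% higher, or 25.8% with median centring). The total was 252 and 229 without 1 h replicates 3 and 4, 228 and 259 without 30 min replicates 3 and 4, and 1049 with array quality weights.

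Over the 17 lists and 12 comparisons, 31 of 204 list tests passed with the preset correlation and 7 with an estimated correlation. Those 7 were the RA pathway at both RA times, paraxial mesoderm at both RA times and in DAPT at 3 h, posterior Hox genes in RA at 3 h and the Wnt pathway in DAPT at 3 h. The lists of cell cycle, heat shock and stress, left-right patterning and notochord genes passed in none of the 12 comparisons, with smallest adjusted p of 0.0575, 0.0884, 0.145 and 0.211. With all probe sets of a list in place of 1 per gene, cell cycle passed in RA at 3 h, notch1a-intra at 90 min and DAPT at 3 h (adjusted p = 0.0439, 0.0384 and 0.026) and heat shock and stress in RA at 3 h (0.0404), and with close pairs averaged cell cycle passed in notch1a-intra at 45 min, as given above. Among the comparisons for which it is not given above, the named genes that kept their call in every alternative run for them were 11 of 16 called in dnfgfr1 at 30 min and 7 of 16 at 1 h, 13 of 20 in DeltaTcf, 15 of 20 in dkk1, 13 of 19 in wnt8a and 7 of 16 in wild type, and 13 of 17 in dkk1 and 12 of 14 in DeltaTcf against wnt8a and 10 of 14 in DeltaTcf against dkk1.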

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

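The tests of a swap and of the time for notch1a, of batch and of a response of dkk1b itself, and of opposite Wnt effects were chosen after results were seen, and the other tests were written before their values were computed. A difference between times, tested as an interaction, singled out the results that follow, and a test for a single array far from the rest of its group found none in the 19 sets of target gene values tested. That test does not see 2 arrays apart from 2 others, as for notch1a at 45 min. The RA effect differed between 3 h and 1.5 h at 73 probe sets, that of dnfgfr1 between 1 h and 30 min at 38, that of notch1a-intra between 90 and 45 min at 70 and that of DAPT between 3 h and 1.5 h at 401.

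For RA, the later effect minus the earlier was 1.66 for dhrs3a, 2.13 for meis2b, 1.30 for nr2f1a, 2.78 for rx3, -1.75 for hoxc11a, -3.69 for lgals3b, -1.26 for phc2a, -1.78 for hoxd11a and -2.11 for arhgap29b on the log2 scale. For dnfgfr1 it was -3.68 for lgals3b, -4.35 for sde2, -2.21 for rnf19a, 1.57 for slc15a4, -1.91 for spry4, 2.80 for grb2b, -2.48 for ier2a, -2.14 for mespaa and -1.23 for dusp6. For notch1a-intra it was 2.54 for igfbp1a, 3.51 for inaa, 2.37 for gcdhb, -3.20 for lmbr1l and -2.48 for psap, of which inaa and lmbr1l were not called without the 2 libraries of low notch1a (adjusted p = 0.138 and 0.228). For DAPT it was -1.08 for sec24a, -1.38 for snrnp35, 1.86 for msrb1a, -2.64 for her2, 2.96 for nanos3, 2.61 for ctss2.1, 1.86 for phlda2, 2.14 for tdrd7a, -2.72 for mettl13, -2.84 for ints7, -1.64 for epha4a and -2.42 for ccdc34.

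The raised dkk1b in the libraries labelled DeltaTcf (12.81 against 5.44 in wild type) was weighed against its label. Embryos of the dkk1 line under that label should have left few differences between the 2 groups, but the probe sets called between DeltaTcf and dkk1 came to 1.06 times those called between dkk1 and wnt8a. The limit written beforehand was passed, which spoke against a wrong label, yet a check chosen afterwards found that DMSO groups of separate experiments differed by 1705 and 2914 probe sets, more than the 352 here, so a wrong label may still apply. A batch effect shared with the wnt8a libraries was excluded, since dkk1b there lay 0.10 from wild type. The labels give no batch, so an effect that spared those libraries was not tested. A response of dkk1b itself to DeltaTcf stayed open, with dkk1b at -0.25 against the dkk1 libraries. In dnfgfr1 at 30 min and in wnt8a axin2 fell against wild type without raised dkk1b (4.67 and 5.53). But axin2 there lay at 7.97 and 8.08 against 5.83 in DeltaTcf, so these groups do not decide the question. The fall in wnt8a also belongs to the shift that all Wnt groups shared, which cannot be parted from batch. No group other than dkk1 had axin2 within 1 of the DeltaTcf level.

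The low notch1a in 2 of the 4 libraries labelled notch1a-intra at 45 min was weighed next. A swap with a gal4 library was excluded, since the highest gal4 library lay at -3.38 from the 90 min mean. That 45 min is too early in every embryo was ruled out by the high libraries themselves, the highest at -0.0232 from that mean, while a later start in the other 2 was not tested. Embryos without the transgenes under that label may account for it: over 375 probe sets raised at 90 min the median difference from gal4 in replicates 2 and 4 was 0.13 and 0.13, against 0.46 and 0.47 in replicates 1 and 3. The ratio of 0.281 fell between the limits written beforehand, so this stayed open. Against the same-numbered gal4 libraries the medians were 0.0507 in replicate 2 and 0.204 in replicate 4, so these were less alike there. Replicates 1 and 3 were at 0.462 and 0.497.

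The 915 probe sets that changed alike in all 3 Wnt groups were weighed last. Unusual wild-type controls were excluded, since 5.36% of them were called in that direction in dnfgfr1 at 1 h against the same controls. A difference between library batches could account for them, with 61.1% called in that direction in each of the 3 groups against dnfgfr1, but no group spans both experiments, so batch and treatment cannot be parted. Of these probe sets 2.84% were called between dkk1 and wnt8a, under the limit written beforehand for the Wnt manipulations themselves, but they were chosen for moving alike, so that test decides nothing. Of the calls shared by wnt8a and dkk1 with split controls 0.333% went opposite ways, but a shift common to both groups would hide opposite effects, so these stayed open.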

How the results depend on the processing

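The comparisons within the Wnt groups, wild type at 30 min as control, the runs without the low-notch1a libraries and the averaged close pairs were chosen after seeing the data. Of 315 calls of named genes, a gene counted once in each comparison, 174 held in every alternative run for them and 141 were lost or turned in at least 1. The stricter filter was not run for 74 of these calls, whose genes it removes, 46 of them among the 174. The cause was not tested. The reversed differences were lgals3b at 0.31 in dkk1 and 0.75 in wnt8a and dact2 at -0.10 in wnt8a with wild type at 30 min as control, and ret at -0.13 (up to 3.39) and hnf1bb at -0.20 (up to 3.11) without DAPT 3 h replicate 1 (replicate 2). Among differences not called, tcf7l1a in DeltaTcf against dkk1 was 0.00854 with the deposited scaling, and -0.17 to 0.0534 with an array left out, the highest without DeltaTcf replicate 3. In dnfgfr1 at 1 h fgfr1a was -0.00932 with median centring, -0.00147 with a pseudocount of 64, -0.0109 with array weights, and -0.0789 to 0.0978 with an array left out, negative without dnfgfr1 replicates 1 and 4 (-0.00174 and -0.00296) and wild-type replicates 3 and 4 (-0.071 and -0.0789). At 30 min fgfr1a was -0.0058 with a pseudocount of 1, and -0.15 to 0.17 with an array left out, negative without dnfgfr1 replicate 3 and wild-type replicates 1 and 2 (-0.15, -0.0073 and -0.0425). With array weights hey1 and her4.2 were -0.49 and -0.23 in notch1a-intra at 45 min, and dkk1b in wnt8a was -0.14 to 0.26 with an array left out, negative without replicate 4 of wild type or of wnt8a (-0.14 and -0.00635). With median centring DAPT at 3 h had 315 calls, its time effect 221 and DeltaTcf against dkk1 230. The RA time effect had 46 with a pseudocount of 1 and 41 with the stricter filter. With array weights the counts were RA 1.5 h 1068, RA 3 h 725, dnfgfr1 30 min 861, 1 h 595, wnt8a 2539, notch1a-intra 45 min 2651, DAPT 1.5 h 196, DAPT 3 h 35, wild type 1049, dkk1 against wnt8a 604, DeltaTcf against wnt8a 436, and for the time effects of RA, dnfgfr1, notch1a-intra and DAPT 362, 141, 1341 and 42. In a fit of the compared groups alone they were dnfgfr1 1 h 229, notch1a-intra 45 min 61, 90 min 329, DAPT 1.5 h 7, DAPT 3 h 78, DeltaTcf against dkk1 176, and 21 and 11 for the notch1a-intra and DAPT time effects. With the replicate block they were RA 1.5 h 277, dnfgfr1 1 h 139, notch1a-intra 45 min 158, 90 min 297, DAPT 3 h 88, wild type 140, DeltaTcf against dkk1 199, and 30, 10 and 6 for the RA, dnfgfr1 and DAPT time effects. In limma with the block DAPT at 1.5 h had 0, with 1058 at an unadjusted p under 0.05 in that fit. Only for notch1a-intra at 45 min did all same-numbered arrays correlate at 0.21 or more, and 3 of the 4 pairs had their highest r with the same number. Whether the numbers pair those samples is thus not settled. Elsewhere same-numbered arrays had r between -0.258 and 0.217. For notch1a-intra at 90 min 3 of 4 pairs also had their highest r with the same number, with r of 0.0446 to 0.116 over the pairs. In DAPT at 3 h 2 of 2 pairs did, at 0.104 and 0.171, so pairing is not settled there either. Without the low-notch1a libraries notch1a-intra at 45 min had 1187 and its time effect 125, from replicates 1 and 3, themselves a close pair. With close pairs averaged the counts were 64 and 14, with 218 at 90 min. Against wild type at 30 min wnt8a had 2643. List shifts were 31 with the preset and 7 with an estimated correlation. With split controls shared calls were 674.5, 548, 466.2, 28.5 and 23. Leaving out each array in turn gave RA 1.5 h 246 to 531, RA 3 h 283 to 335, dnfgfr1 30 min 201 to 274, 1 h 233 to 301, DeltaTcf 1628 to 1862, dkk1 2104 to 2185, wnt8a 1284 to 1442, notch1a-intra 45 min 244 to 524, 90 min 434 to 704, DAPT 1.5 h 225 to 429, DAPT 3 h 170 to 723, wild type 228 to 441, dkk1 against wnt8a 199 to 268, DeltaTcf against wnt8a 161 to 251, DeltaTcf against dkk1 191 to 329, and time effects of RA 43 to 94, dnfgfr1 27 to 42, notch1a-intra 31 to 129 and DAPT 218 to 492. Without either DAPT 3 h array the lone one is assumed to vary like the other groups. Signal over background limits dim genes, whose changes a pseudocount of 16 understates.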

Other observations

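The germ cell markers were chosen after the rise of 3 genes was seen, and their limit was written before they were tested. In the DAPT libraries at 3 h, the germ cell genes nanos3, dnd1 and tdrd7a were at 5.57, 7.40 and 5.73 in replicate 1 and at 9.55, 9.71 and 7.29 in replicate 2. Germ cells in the dissected tissue may account for this: in replicate 2, 37.5% of 8 other germ cell markers (ddx4, h1m and kop) lay above every library of the other groups. That share lay between the limits written beforehand, so the hypothesis stayed open. The ddx4 level was 6.01 in replicate 1 and 6.13 in replicate 2, against 5.26 in the highest library of the other groups, so ddx4 did not follow the difference between the replicates, while h1m and kop were at 4.42 and 4.19 in replicate 1 and at 5.63 and 5.29 in replicate 2.

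Regrouping the arrays at random tested whether chance could give the counts of calls. In each comparison of 4 arrays with 4 or 3, except notch1a-intra at 45 min, 1 of 35 splits, the real one, called as many. Chance alone ranks the real split first in 1 of 35 cases, and the test was repeated over many comparisons. A first rank thus does not exclude chance in each of them. The closest was DAPT at 1.5 h, with 414 calls against 291 in the highest other split. For notch1a-intra at 90 min the real split called 696 and the highest other 209. The splits there count close replicate pairs as separate samples, which is not settled, so that rank decides less. For notch1a-intra at 45 min 2 of 35 splits called as many, the other calling 1906, so chance was not excluded; that split parted replicates 1 and 3 from 2 and 4, which points to a structure of the samples. Among the 8 splits that part every same-numbered pair, the real one called 414 and the highest other 169. Among 100 regroupings, the real one included, 4 called as many as the 73 of the RA effect between times, under the limit written beforehand. With so few regroupings drawn, that share lies too near the limit to exclude chance. The highest other called 377, which points to a structure of the samples there too. For the dnfgfr1 and notch1a-intra effects 7 and 22 called as many as the real 38 and 70, the highest others calling 297 and 1897, so chance was not excluded. DAPT at 3 h, with 2 arrays, had no such test.

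Some replicates of the Notch experiment lay closer together than others. Over 4629 bright probe sets the SD of the difference was 0.224 for gal4 45 min replicates 1 and 3, 0.235 and 0.317 for notch1a-intra 45 min replicates 2 and 4 and replicates 1 and 3, and 0.197 and 0.231 for the same pairs at 90 min. The lowest value in the other groups was 0.286, for DAPT 1.5 h replicates 2 and 3, below the 0.317 of notch1a-intra 45 min replicates 1 and 3. The other DAPT 1.5 h pairs were at 0.583 and 0.564, and that close pair was not averaged. Whether the close pairs share embryos or RNA was not tested. If they do, the notch1a-intra groups hold 2 separate samples each and gal4 at 45 min 3, so the p values that count 4 arrays, with or without the block, could be too small. With close pairs averaged the calls were 64 at 45 min, 218 at 90 min and 14 for the time effect.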
